A study of Rattus norvegicus with 743 samples.

How the data were processed

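Rat liver RNA was sequenced in 377 treated and 366 vehicle libraries, per the labels' protocols with MagMAX extraction from frozen tissue and TruSeq Stranded mRNA libraries. The deposited tables hold expected counts per gene, as their values show: at least 0, 87.49% of the non-zero values whole, and not normalised. Genome build Rnor_6.0 is given in the submitters' processing notes; the aligner and the quantifier are not stated. The table with Ensembl identifiers (32893 rows) was analysed, and a deposited table of expected counts over RefSeq genes (34335 rows, 92.46% of the non-zero values whole), called the other gene table here, was an alternative. The deposited FPKM tables were not used, since a count model needs counts. A row for the Ugt1a locus equals the sum of its 10 transcript rows to within 0.044 reads in every library, so the locus row was dropped and the transcript rows kept. Where a symbol of a list stood on more than 1 row (4265 rows share their symbol with another), the row with most counts was taken. The tables give no coordinates.

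Groups were read from the labels' treatment, study, batch number, vehicle and strain. Libraries of 1 animal were summed, values were rounded, and n counts animals. Each treated group was compared with the vehicle group of its study, batch number and vehicle in edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, robust dispersions and the quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Sex was a covariate for bardoxolone. Contrasts of drugs in 1 study compared the treated groups directly. Those of drugs in different studies compared effects, each against its own vehicle group, in 1 fit of 4 groups. The lapatinib repeat used the replicate as a block. Its pairing was checked: deviations from the group mean of 1 animal correlated between batches at 0.49 to 0.663 across genes, and those of different animals at most at −0.016. CPM values, counts scaled to a common library total, use the TMM factors of the fit at hand, so group means differ slightly between fits. Fold changes are log2 and printed with SE, group means with SD. Intervals of 95% cover the variation between animals as the model estimates it.

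Gene lists (29, with 427 entries, of which 400 matched by symbol, 2 by an older symbol and 25 not) were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Adjustment was over all lists and comparisons together, or over the lists of a contrast or later fit. A call is said to hold if camera with an estimated correlation also passed. fry asked whether a list moved 1 way on balance. Lists share members, most often NRF2 (9 of 28 matched genes are in another list) and CAR (5 of 14). Cyp2b1 and Cyp2b2, Cyp4a2 and Cyp4a3, the Cyp3a genes, the Gsta genes and the Ugt1a transcripts are near-identical in parts, so reads may be shared among them and their separate values are less certain than their sums.

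Named genes followed a rule. These were the members of leading lists, and the 8 largest increases and 8 largest decreases past the threshold with a mean CPM of at least 5 in the higher group. All treated animals had to lie on 1 side of all vehicle animals, except in contrasts. At most 4 members of other called lists were added, and across treatments 15 indicator genes and the 3 leading comparisons of each list. Genes without a symbol were passed over (at most 5 per comparison and direction), and some genes that met the rule are not reported here. The comparisons, the lists, this rule and the alternatives, apart from those named as chosen later, were set before the data were examined.

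Alternatives were RLE size factors, DESeq2 1.42.0, no count filter, the other gene table, a minimum absolute log2 fold change of 1, each animal left out, 1 fit across all animals, RIN as a covariate, the nearest control library, libraries of RIN under 7 removed, no sex covariate and no replicate block. Tested on simulated data built on these counts, the TCDD comparison recovered 87.8% of 98 genes changed by a log2 fold of 1 and 97.9% of 97 changed by 2. For the contrast of phenobarbital between strains, recovery was 21% and 70% of 100 genes each.

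A clock score was the mean log2 CPM of Dbp, Per3, Per2, Tef, Nr1d2 and Ciart minus that of Arntl, Npas2 and Clock, and an interferon score the mean log2 CPM of the 14 genes of that list. A noise index compared pairs of libraries: the mean over genes with at least 20 counts in the pair of the squared deviation from a split in proportion to library totals, divided by its binomial variance, so that pure counting noise gives a value near 1.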

Results

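Liver RNA was sequenced from rats given pharmaceuticals or reference toxicants by repeated daily dosing and killed 24 hours after the last dose, per the labels. The set came from 680 animals, with 414 libraries of Han Wistar and 329 of Sprague Dawley rats, 726 of males and 17 of females. They fell into 99 treated groups of 95 treatments (377 libraries) and 83 vehicle groups (366 libraries) of 75 studies, with 18 vehicles, 7 sequencing batch numbers and 49 flow cells. Compared groups held 2 to 6 animals, most often 4. Library totals ran from 0.312 to 45.5 M counts with a median of 18.19 M. Every library outside the PCN study had at least 11.2 M. RNA integrity numbers (RIN) ran from 2.2 to 9.5 with a median of 8.4, and 25 libraries were below 7. Each treated group was compared with the vehicle group of its own study, which gave 97 comparisons. The mean RIN was higher in the treated group in 71 of them, lower in 25 and the same in 1, with a median difference of 0.2.

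Treatments differed widely in how many liver genes they changed. Azithromycin changed 6032 of 12811 genes tested (3177 higher, 2855 lower), ticlopidine 5997, flutamide 5973, fluoxetine 5953, ritonavir 5346, carbamazepine 5095, the compound coded Cmpd Z 5074, naproxen 4892 with 2 treated animals, sudoxicam 4678 and almorexant 4481. At least 100 genes passed in 59 of the 97 comparisons and at least 1000 in 32, and the median was 342. The almorexant count was 2983 without vehicle replicate 2. Of the 59, 8 had over 60% of their calls higher and 3 under 40%. Most changed genes fell after co-amoxiclav (480 higher and 1209 lower) and levofloxacin (10 higher and 223 lower). Together these 1689 genes for co-amoxiclav were 974 without treated replicate 1, and 1009 and 1024 without vehicle replicates 1 and 3. The 233 for levofloxacin were 151 without treated replicate 1 and 139 without vehicle replicate 1. In 16 comparisons edgeR called 0 genes, among them acetaminophen (159 genes at an unadjusted p under 0.05), dipyridamole (2068), erythromycin (1546), lapatinib (1117) and phenobarbital in Han Wistar rats (2468). DESeq2 called between 4 and 648 genes in these 16. Leaving out each animal in turn, in the 94 comparisons with at least 3 animals per arm, left 42 at 100 genes or more in every run. Of those at 100 or more, 14 fell below it in some run, and 6 under 100 reached it. Every count stayed within 1.5 times in only 14 of the 94.

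**Figure D1:**
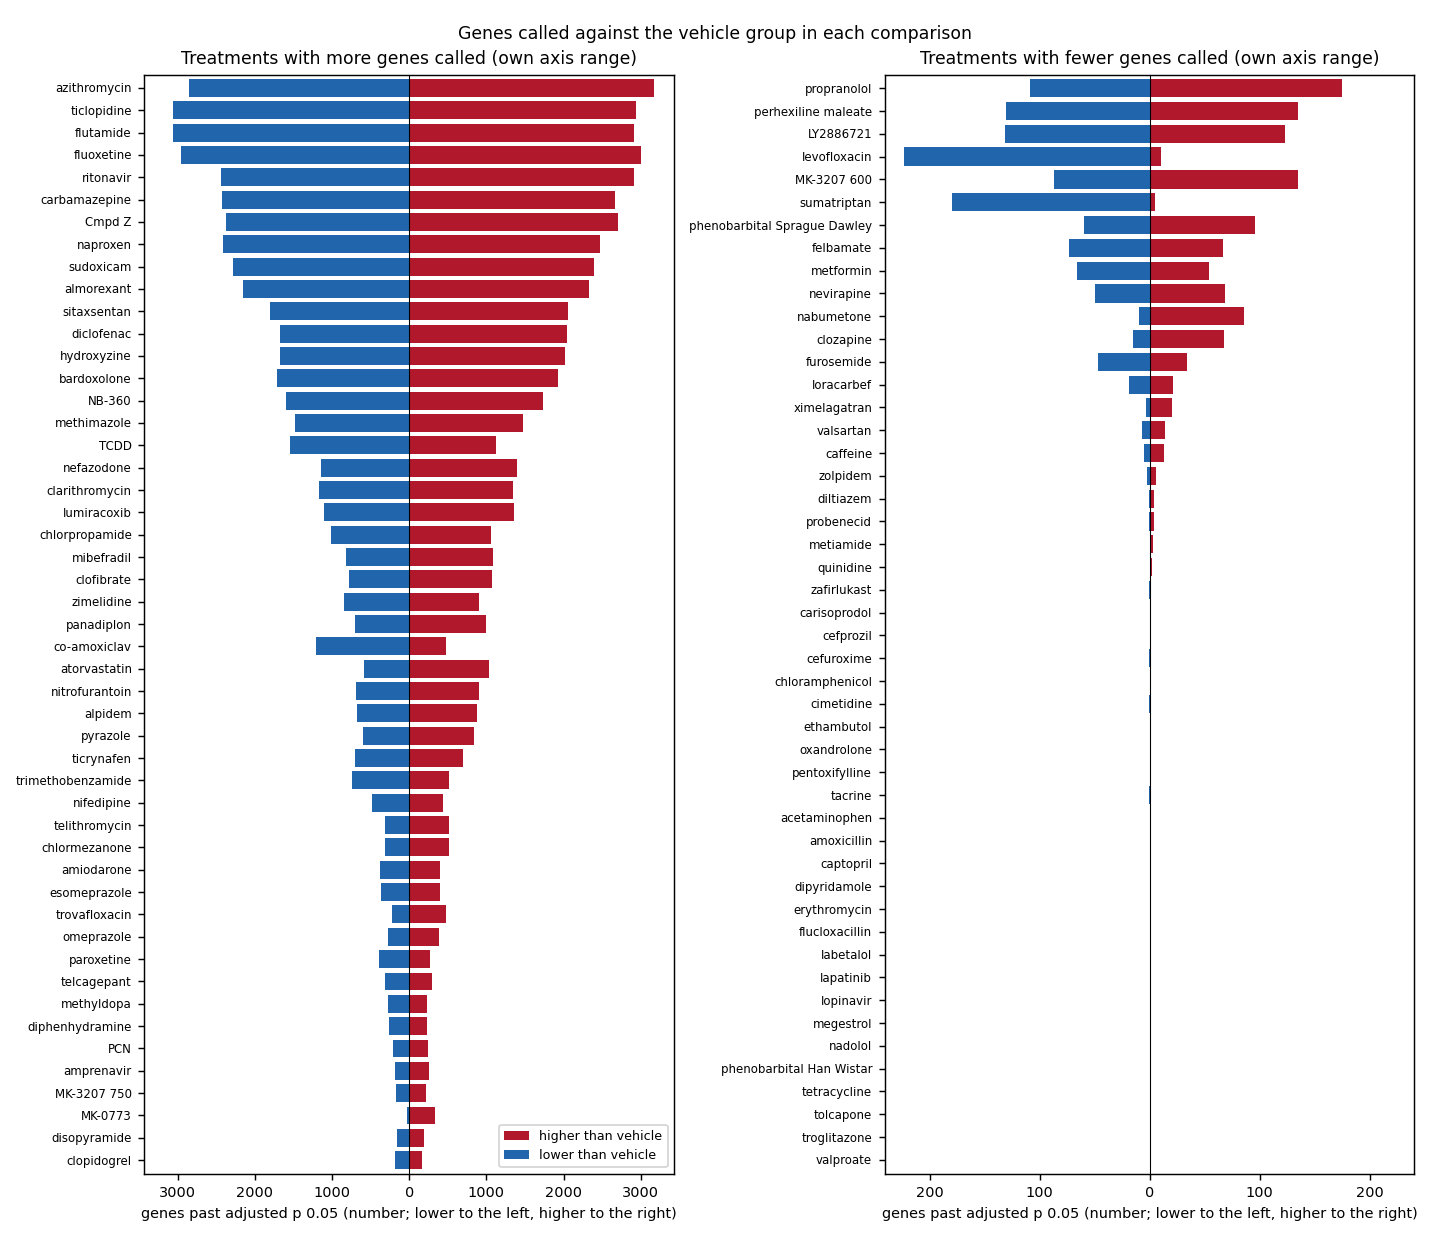
Genes past an adjusted p of 0.05 in each of the 97 comparisons, as horizontal bars with the number lower than vehicle to the left and the number higher to the right, in 2 panels with their own axis ranges. Bars run from 6032 genes for azithromycin to 0 genes in 16 comparisons.

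Targets of xenobiotic receptors were called higher after many treatments. The list of targets of the aryl hydrocarbon receptor (AhR) was higher than other genes in 55 comparisons and lower in 1, and 6 of these calls held with an estimated correlation between genes. Cyp1a1, the classical AhR-induced cytochrome P450 (ENSRNOG00000019500), rose in 27 of 94 comparisons. Outside TCDD its largest rises were from 1.71 to 4690 ± 830 CPM after flutamide (SD, n = 4), from 1.69 to 2190 CPM after almorexant and from 1.44 to 1680 CPM after Cmpd Z. It fell only after co-amoxiclav (3.08 to 0.205 CPM). In the list as a whole 7 of 9 members rose after flutamide (7 adjusted over the list alone, adjusted p = 0.0405 with an estimated correlation) and 5 of 7 after NB-360 (5 adjusted over the list alone, adjusted p = 0.0405 with an estimated correlation). Targets of the constitutive androstane receptor (CAR) were called higher in 67 comparisons and lower in 6, with 17 calls held. After carbamazepine 13 of 14 rose and 1 fell, the same counts adjusted over the list alone, with Cyp2b1 (ENSRNOG00000033680) going from 274 to 11700 CPM. Hydroxyzine raised 13 of 14 and ticlopidine 13 of 14 with 1 lower, again the same adjusted over the list alone. Cyp2b1 rose in 24 comparisons, from 18.5 to 3010 CPM after nevirapine, and fell in 6, from 134 to 1.18 CPM after telcagepant.

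The list of pregnane X receptor (PXR) targets was called higher in 45 comparisons and lower in 8, with 6 calls held. Cyp3a23/3a1 (ENSRNOG00000032560), a rat CYP3A gene, rose in 30 comparisons and fell in 8. It went from 3080 to 85900 CPM after almorexant, from 2810 to 46700 CPM after ritonavir and from 3300 to 44000 CPM after telithromycin. It fell from 3440 to 357 CPM after naproxen and from 4310 to 514 CPM after azithromycin. Of 9 PXR targets 8 rose after clarithromycin (8 adjusted over the list alone, adjusted p = 0.0109 with an estimated correlation) and 7 after NB-360 (8 adjusted over the list alone, adjusted p = 0.0253 with an estimated correlation). After naproxen 7 of 8 fell (7, with 1 higher, adjusted over the list alone, adjusted p = 0.0886 with an estimated correlation). Targets of NRF2, the regulator of the antioxidant response, were called higher in 68 comparisons and lower in 8, with 6 calls held. After flutamide 26 of 27 rose (26 adjusted over the list alone, adjusted p = 0.0849 with an estimated correlation), with the quinone reductase gene Nqo1 going from 25.8 to 905 CPM. Carbamazepine raised 25 of 27 (27 adjusted over the list alone, adjusted p = 0.0763 with an estimated correlation) and ticlopidine 25 (25 adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation). Naproxen lowered 15 of the 27 and raised 3 (16 and 3 adjusted over the list alone, adjusted p = 0.413 with an estimated correlation). Nqo1 rose in 33 comparisons and the sulfiredoxin gene Srxn1 in 21.

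Lipid genes moved in opposite directions across lists. PPARalpha targets, many of them genes of fatty acid oxidation, were called lower in 54 comparisons and higher in 16, and only 1 call held with an estimated correlation. Fluoxetine lowered 26 of 28 (26 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation), NB-360 25 of 27 (25, with 1 higher, adjusted over the list alone, adjusted p = 0.0732 with an estimated correlation) and ritonavir 23 of 28 (23 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). Cyp4a1 fell in 24 comparisons, from 788 to 56.4 CPM after almorexant, and rose in 2, clofibrate and amiodarone (716 to 1900 CPM). Amiodarone raised 15 of 28 PPARalpha targets (17 adjusted over the list alone, adjusted p = 0.181 with an estimated correlation). Cholesterol synthesis genes were called higher in 45 comparisons and lower in 13, and 0 of these calls held. Zimelidine raised all 25 (25 adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), as did Cmpd Z (25 adjusted over the list alone, adjusted p = 0.133 with an estimated correlation). The squalene epoxidase gene Sqle went from 14.1 to 228 CPM after fluoxetine. Fatty acid synthesis genes were called higher in 28 comparisons and lower in 11, with 0 held. After amiodarone 12 of 14 rose (12, with 1 lower, adjusted over the list alone, adjusted p = 0.0509 with an estimated correlation) and 12 of 14 after zimelidine (12 adjusted over the list alone, adjusted p = 0.068 with an estimated correlation). Bile acid genes were called lower in 24 comparisons and higher in 4, with 0 held. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, went from 118 to 4.7 CPM after ritonavir and from 22.7 to 201 CPM after nitrofurantoin.

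Acute phase genes and neutrophil markers rose after several treatments. A2m, an acute phase protein of the rat, went from 32.2 to 23000 ± 3080 CPM after naproxen (SD, n = 2), from 18.6 to 12000 CPM after lumiracoxib, from 21.5 to 11400 CPM after diclofenac and from 46 to 22500 CPM after sudoxicam. Of 17 acute phase genes 15 rose after lumiracoxib (15 adjusted over the list alone, adjusted p = 0.0538 with an estimated correlation), 15 after sudoxicam (15 adjusted over the list alone, adjusted p = 0.085 with an estimated correlation) and 16 after fluoxetine (16 adjusted over the list alone, adjusted p = 0.165 with an estimated correlation). All tested neutrophil markers rose after lumiracoxib (6 of 6, median log2 fold change 5.89; adjusted p = 0.118 with an estimated correlation), sudoxicam (5 of 5; adjusted p = 0.168 with an estimated correlation) and diclofenac (4 of 4; adjusted p = 0.0957 with an estimated correlation), the same counts adjusted over the list alone. The list was also called after naproxen (4 of 4; adjusted p = 0.271 with an estimated correlation), fluoxetine (4 of 4; adjusted p = 0.458 with an estimated correlation), mibefradil (4 of 5; adjusted p = 0.411 with an estimated correlation) and sitaxsentan (3 of 4, 4 adjusted over the list alone, adjusted p = 0.374 with an estimated correlation), and was called higher in 9 comparisons in all. Adjusted over the list alone, the counts after naproxen, fluoxetine and mibefradil were the same. Of the 9 matched neutrophil markers, those with too few counts in both arms were not tested, which favours markers that rose. Cyp2c11, the main male-specific P450, fell from 1510 to 0.962 CPM after naproxen, from 1450 to 3.19 CPM after sudoxicam and from 931 to 3.59 CPM after diclofenac. It fell in 20 comparisons and rose in 0 at an adjusted p of 0.05. Across all treatments the acute phase list was called higher in 24 comparisons and lower in 15. After flutamide 14 of 17 members fell with 1 higher (the same adjusted over the list alone, adjusted p = 0.199 with an estimated correlation). The glucocorticoid-responsive list was called higher in 13 comparisons and lower in 12.

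Stress and growth lists were called in both directions. The ATF4 stress response list was called higher in 29 comparisons and lower in 6. Carbamazepine raised 15 of 21 and lowered 1 (17 and 2 adjusted over the list alone, adjusted p = 0.167 with an estimated correlation), with asparagine synthetase, Asns, going from 1.06 to 24.3 CPM. Asns rose in 24 comparisons and fell in 0. ER chaperones were called higher in 26 comparisons and lower in 20. The heat shock list was higher in 10 and lower in 17. The p53 list was higher in 9 and lower in 4. The p53 target Cdkn1a went from 1.39 to 52.4 CPM after propranolol and from 30.7 to 1.37 CPM after NB-360. Proliferation genes were higher in 25 and lower in 37, with 2 of the calls lower held. Panadiplon raised 27 of 29 (27 adjusted over the list alone, adjusted p = 0.218 with an estimated correlation), the proliferation marker Mki67 from 7.24 to 27.3 CPM. LY2886721 lowered 15 of 26 (18 adjusted over the list alone, adjusted p = 0.0253 with an estimated correlation). Immediate early genes were higher in 5 and lower in 24. Interferon genes were higher in 17 and lower in 30. Ritonavir raised 14 of 14 (14 adjusted over the list alone, adjusted p = 0.374 with an estimated correlation) and azithromycin 13 of 14 (14 adjusted over the list alone, adjusted p = 0.318 with an estimated correlation). Clock genes were lower in 9 and higher in 1.

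Hepatocyte and cell type lists moved mainly downward. Hepatocyte genes were called lower in 35 comparisons and higher in 7, and 15 of 17 fell after azithromycin (15, with 1 higher, adjusted over the list alone, adjusted p = 0.0661 with an estimated correlation). Male-predominant genes were lower in 35 and higher in 5. Female-predominant genes were higher in 22 and lower in 4. Macrophage markers were lower in 45 and higher in 13. All 12 fell after methimazole (12 adjusted over the list alone, adjusted p = 0.282 with an estimated correlation) and after ticlopidine (12 adjusted over the list alone, adjusted p = 0.251 with an estimated correlation). After lumiracoxib 10 rose (11 adjusted over the list alone, adjusted p = 0.278 with an estimated correlation). Lymphocyte markers were lower in 27 and higher in 1. Erythroid markers were lower in 45 and higher in 6, with 1 call held. Stellate and fibroblast markers were lower in 35 and higher in 10. Endothelial markers were lower in 25 and higher in 9. Cholangiocyte markers were higher in 4 comparisons and pancreas markers in 1, diphenhydramine. No call of the lists for which no held call is given here held with an estimated correlation.

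**Figure D2:**
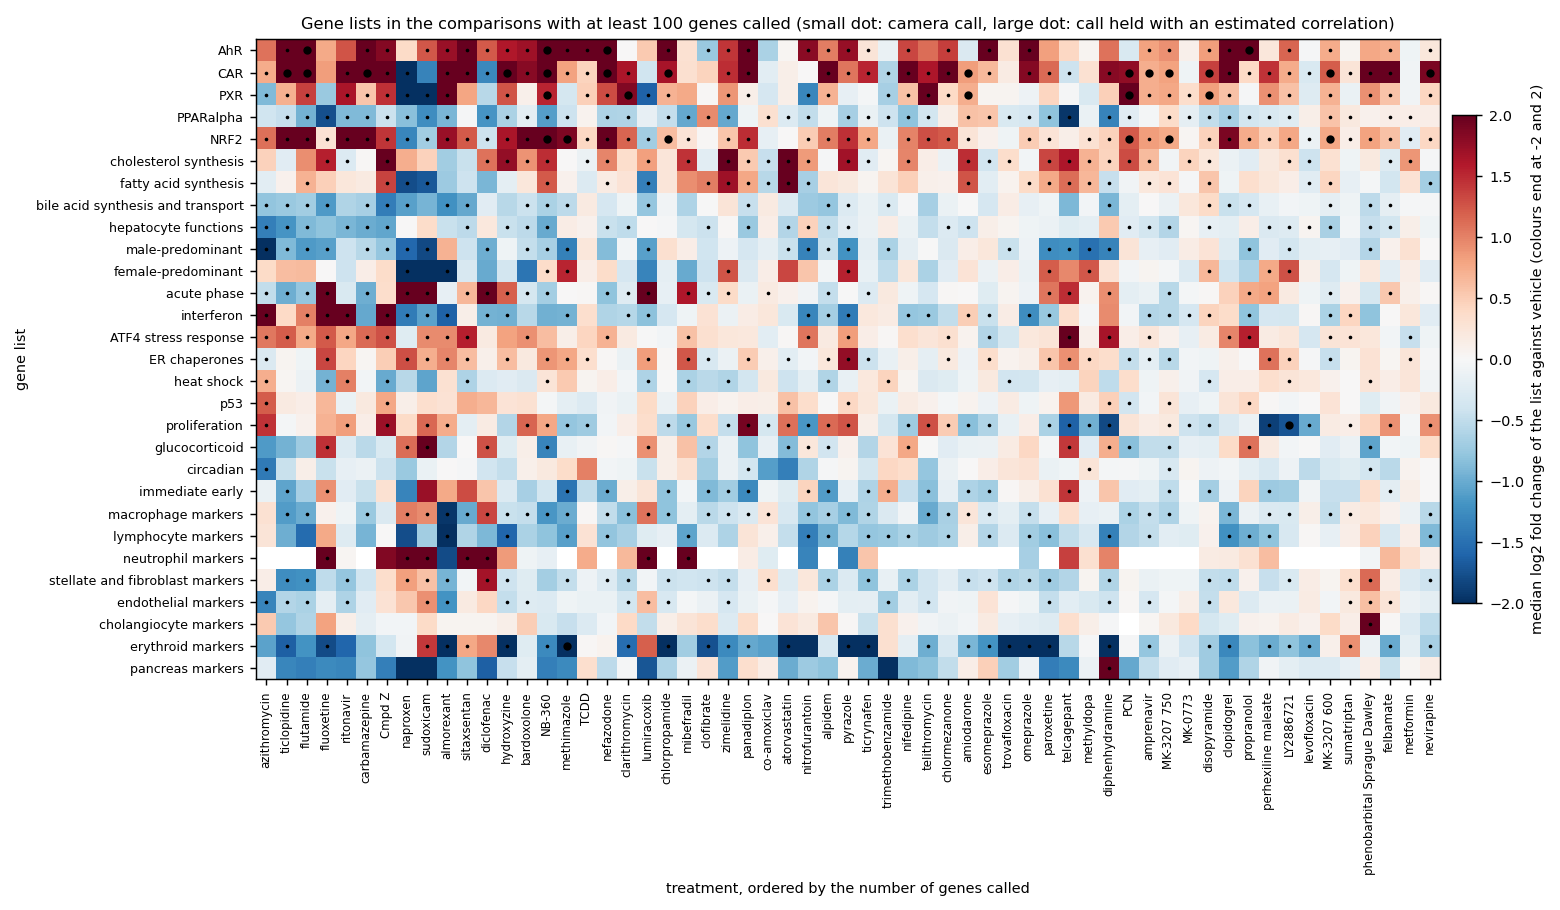
Median log2 fold change against vehicle of each of the 29 gene lists (rows) in the 59 comparisons with at least 100 genes called (columns, ordered by that number), as colours that end at -2 and 2; white cells were not tested. A small dot is a camera call and a large dot a call that held with an estimated correlation, which the CAR list had most often, in 17 of all 97 comparisons.

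TCDD, a dioxin and prototype AhR agonist, was given at 0.00015 mg/kg per day for 4 days to Han Wistar rats. The AhR target genes led the change: 6 of 7 tested members of that list rose, also 6 when adjusted over the list alone. Cyp1a1 went from 1 ± 0.952 CPM in vehicle rats to 4330 ± 728 CPM (SD, n = 4 in each group). Its log2 fold change was 12 ± 0.629 (SE, adjusted p = 4.35e-05). Cyp1b1 rose by a log2 fold change of 11.02 ± 0.474, to 350 ± 145 CPM, and Cyp1a2 by 3.59 ± 0.272, from 707 ± 236 to 8530 ± 1920 CPM. The glucuronosyltransferases Ugt1a6 (log2 fold change 3.15) and Ugt1a7c (2.94) and the quinone reductase Nqo1 (2.4) rose as well, whereas the AhR-induced repressor Tiparp had a log2 fold change of 0.31 with an adjusted p of 0.194. The list test gave an adjusted p of 1.03e-26, and an adjusted p = 0.0539 with an estimated correlation.

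Counting the 6 AhR targets, 2673 of the genes tested differed after TCDD, 1123 higher and 1550 lower. Of the NRF2 targets 10 of 26 rose (14, with 1 lower, adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation). In the CAR list 3 of 13 rose (7 adjusted over the list alone, adjusted p = 0.413 with an estimated correlation). In the PXR list 3 of 9 rose (3 adjusted over the list alone, adjusted p = 0.219 with an estimated correlation), including Cyp3a62 (log2 fold change 1.71) and Gsta2 (1.44). Cholesterol synthesis genes were called lower as a list with 5 of 25 members down (6 adjusted over the list alone, adjusted p = 0.736 with an estimated correlation). With RIN as a covariate this direction reversed (adjusted p = 0.178). Insig1, a sterol-regulated gene, fell from 103 to 31.7 CPM. Genes of the circadian clock moved in opposite directions. The clock output gene Dbp rose from 2.92 to 68.9 CPM and Per3 from 3.88 to 42.8 CPM, while the activators Arntl (log2 fold change −3.83, from 28.8 to 1.99 CPM) and Npas2 (−3.06) fell. The steroid dehydrogenase gene Hsd17b2 rose by 2.68, and the cell cycle inhibitor Cdkn1a (−3.47), Zbtb16 (−3) and the taurine transporter Slc6a6 (−2.83) fell. The mean RIN was 9.2 in the TCDD group and 7.88 in the vehicle group, and with RIN as a covariate 49 genes were called. Without vehicle replicate 2 the count was 1684.

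**Figure D3:**
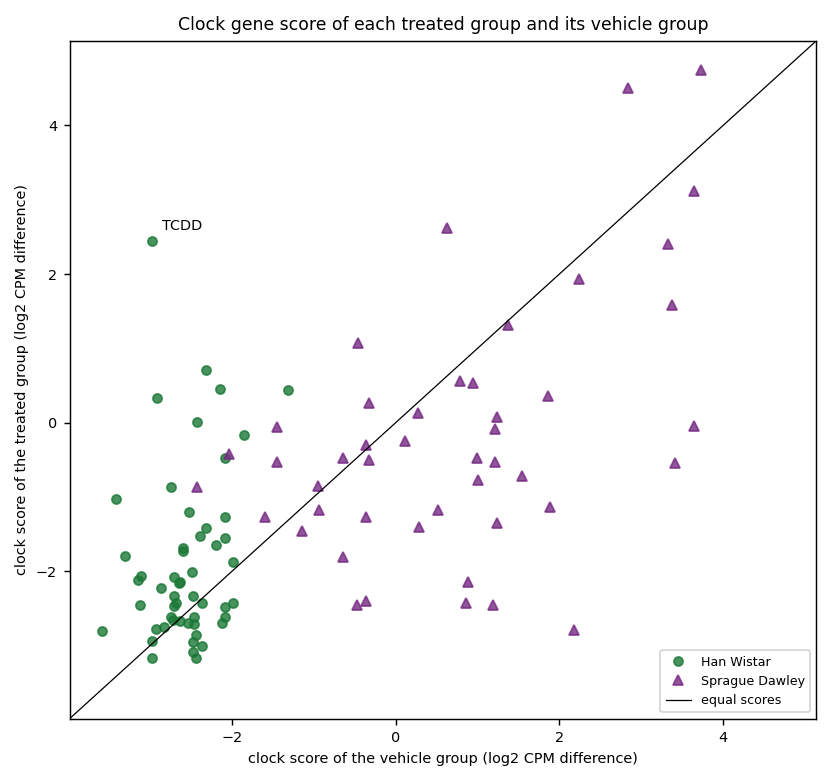
Clock score (log2 CPM, mean of 6 clock genes including Dbp and Per3 minus mean of 3 including Arntl) of each treated group on the vertical axis against that of its vehicle group on the horizontal axis, with circles for Han Wistar and triangles for Sprague Dawley rats and a line at equal scores. The TCDD group lies at 2.45 against −2.98 in its vehicle group.

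Pregnenolone 16alpha-carbonitrile (PCN), the prototype PXR activator in rats, was given at 500 mg/kg per day for 7 days. All 8 tested PXR targets rose, 8 also when adjusted over the list alone, and the list was called with an adjusted p = 0.0179 with an estimated correlation. Cyp3a23/3a1, the rat CYP3A gene of this list, went from 1680 ± 387 to 39900 ± 5850 CPM (SD, n = 4 in each group), a log2 fold change of 4.57 ± 0.221 (SE, adjusted p = 1.7e-11), and Ugt1a1, also of this list, had a log2 fold change of 2.31. Cyp2c24 rose from 4.17 to 706 CPM (log2 fold change 7.48), the glucuronosyltransferase Ugt1a2 from 4.71 to 272 CPM, and the bile acid and drug transporter Slco1a4 from 135 to 1510 CPM. The sterol transporter Abcg8 went from 9.4 to 158 CPM and the carboxylesterase Ces2a rose by a log2 fold change of 4.49. In the CAR list 9 of 13 members rose (12 adjusted over the list alone), among them Gsta3 (log2 fold change 4.75), Abcc3 (4.69) and Cyp2b2 (2.49, from 129 to 724 CPM). Cyp2b1 had a log2 fold change of 0.8 with an adjusted p of 0.052. In the NRF2 list 16 of 24 rose (17 adjusted over the list alone), including the glutathione transferase gene Gsta5, from 86.9 to 1680 CPM. The CAR and NRF2 calls both had an adjusted p = 0.0179 with an estimated correlation.

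Among other lists after PCN, 17 of 23 cholesterol synthesis genes rose (20 adjusted over the list alone, adjusted p = 0.168 with an estimated correlation), with Msmo1 going from 31.7 to 157 CPM and Sqle rising by a log2 fold change of 1.89. Glucocorticoid-responsive genes fell, 4 of 10 (8 adjusted over the list alone, adjusted p = 0.142 with an estimated correlation): Fkbp5 went from 70.9 to 18.4 CPM and Tsc22d3 fell by 1.35 on the log2 scale. Of the 17 ER chaperones 6 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.346 with an estimated correlation). Of the 25 PPARalpha targets 5 fell and 1 rose (6 and 2 adjusted over the list alone, adjusted p = 0.485 with an estimated correlation), Cyp4a1 by a log2 fold change of −1.71. The steroid 17-hydroxylase gene Cyp17a1 (log2 fold change −3.38), the estrogen receptor gene Esr1 (−2.78) and Ppp1r3c, a glycogen-targeting phosphatase subunit (−2.43, from 302 to 52.3 CPM), were among the largest decreases. In all, 243 genes rose and 208 fell. The PCN libraries held 0.312 to 1.74 M counts and their vehicle libraries 1.332 to 10.02 M, so fewer genes could be tested than in other studies. A fit across all animals called 775.

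Clofibrate, a fibrate and PPARalpha agonist, was given at 600 mg/kg per day for 4 days to Sprague Dawley rats. Of 29 PPARalpha targets 17 rose and 1 fell (19 and 2 adjusted over the list alone). Ehhadh, the peroxisomal bifunctional enzyme, went from 772 ± 282 to 16500 ± 4850 CPM (SD, n = 4 in each group), a log2 fold change of 4.42 ± 0.312 (SE, adjusted p = 0.000233). Acot1, an acyl-CoA thioesterase, rose from 2.29 to 468 ± 614 CPM (7.68 ± 1.29, adjusted p = 0.0103), Cpt1b from 7.58 to 167 CPM, Acaa1a from 335 to 2400 CPM and Cyp4a1 from 860 to 4680 CPM. Cyp4a8 fell (−1.45), and Cpt1a had a log2 fold change of −0.52 with an adjusted p of 0.0704. The list was called with an adjusted p of 1.24e-18, and had an adjusted p = 0.292 with an estimated correlation.

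Fatty acid synthesis genes also rose after clofibrate, 7 of 13 with 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.107 with an estimated correlation). The desaturase gene Scd went from 96.5 to 2100 CPM, the lipogenic regulator Srebf1 from 99.1 to 671 CPM, and the elongase gene Elovl6 rose by 3.11. Apoa4 went from 944 to 75 CPM, and Apoa1 (1700 to 614 CPM) and Apoc3 (2020 to 872 CPM) fell with 5 other members of the hepatocyte list, 7 down and 1 up of 17 (8 and 1 adjusted over the list alone, adjusted p = 0.349 with an estimated correlation). Macrophage markers fell, 8 of 12 (11 adjusted over the list alone, adjusted p = 0.344 with an estimated correlation), as did 3 of 4 erythroid markers (3 adjusted over the list alone, adjusted p = 0.257 with an estimated correlation), Hbb from 333 to 99.9 CPM. In the AhR list 2 of 7 fell (2 adjusted over the list alone, adjusted p = 0.289 with an estimated correlation), Cyp1a2 from 730 to 144 CPM. Of the immediate early genes 4 of 10 fell (5 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation), Egr1 from 44.5 to 6.53 CPM. The water channel gene Aqp3 rose from 0.997 to 69.2 CPM. Otop1 and P2rx5 had 0 counts in the vehicle rats: against a floor of 3 counts over the vehicle group, Otop1 (13.2 ± 12.4 CPM after clofibrate) was at least 274-fold higher and P2rx5 (6.25 ± 6.97 CPM) at least 130-fold higher. In total 1079 genes rose and 782 fell, 1861 together. The count was 812, 1055 and 1083 without vehicle replicates 1, 2 and 3, and 930 and 1072 without clofibrate replicates 1 and 4.

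Bardoxolone, an electrophilic triterpenoid known as an NRF2 activator, was given at 10 mg/kg per day for 4 days to 3 rats of both sexes, compared with 3 vehicle rats with sex as a covariate. NRF2 targets rose, 23 of 28 (24 adjusted over the list alone), with an adjusted p of 2.11e-77 and an adjusted p = 0.0726 with an estimated correlation. Akr7a3, an aldehyde reductase of this list, went from 43 ± 18.1 to 2050 ± 780 CPM (SD, n = 3 in each group), a log2 fold change of 5.6 ± 0.142 (SE, adjusted p = 1.03e-06). Gstp1 rose from 8.7 to 1000 ± 1030 CPM, the cystine transporter gene Slc7a11 from 0.19 to 14 CPM, Ephx1 from 297 to 3640 CPM, Gclc, a subunit of the enzyme that limits glutathione synthesis, from 106 to 941 CPM, and Txnrd1 from 91.3 to 563 CPM. Nqo1 had a log2 fold change of 3.11 with an adjusted p of 0.0821, and Hmox1 of 0.15 with an adjusted p of 0.543.

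Other lists moved in the same livers. Of 21 members of the ATF4 stress response list 10 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.469 with an estimated correlation), with the serine synthesis gene Phgdh at a log2 fold change of 6.27 and asparagine synthetase, Asns, at 4.43. In the cholesterol synthesis list 14 of 25 rose (16 adjusted over the list alone, adjusted p = 0.476 with an estimated correlation). Proliferation genes rose, 14 of 27 (19 adjusted over the list alone, adjusted p = 0.507 with an estimated correlation). Of 17 hepatocyte genes 9 fell and 1 rose (9 and 2 adjusted over the list alone, adjusted p = 0.273 with an estimated correlation), with albumin (Alb) going from 83900 to 51700 CPM and Apoc3 falling by 1.32. Macrophage markers (7 of 12, 9 adjusted over the list alone, adjusted p = 0.58 with an estimated correlation) and endothelial markers (4 of 9, 5 with 1 higher adjusted over the list alone, adjusted p = 0.35 with an estimated correlation) fell as well. Of the PPARalpha targets 5 of 29 fell (5 adjusted over the list alone, adjusted p = 0.683 with an estimated correlation), Pdk4 from 70.5 to 14.9 CPM and Cyp4a1 from 376 to 138 CPM. The aldo-keto reductase gene Akr1b10 rose from 0.883 to 223 ± 301 CPM, and the phosphate transporter gene Slc34a2 (27.5 to 2.95 CPM) and serine dehydratase, Sds (100 to 14.8 CPM), were among the largest decreases. In all 1923 genes rose and 1712 fell. The mean RIN was 8.8 in treated and 7.5 in vehicle rats, and a fit with RIN as a covariate called 16 genes. In that fit the directions of the ATF4 (adjusted p = 0.857) and PPARalpha (0.166) lists reversed. There were 1825 without the sex covariate, 2126 without vehicle replicate 2 and 2097 without bardoxolone replicate 2.

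Atorvastatin, a statin, was given at 600 mg/kg per day for 4 days to Sprague Dawley rats. All 25 cholesterol synthesis genes rose, 25 also when adjusted over the list alone, with an adjusted p of 1.43e-49 and an adjusted p = 0.169 with an estimated correlation. Sqle went from 7.61 ± 4.48 to 556 ± 342 CPM (SD, n = 4 in each group). Its log2 fold change was 6.19 ± 0.737 (SE, adjusted p = 0.00455). Acat2 rose from 2.14 to 253 CPM, Hmgcs1 from 174 to 5160 CPM and Nsdhl from 203 to 744 CPM. Fatty acid synthesis genes rose too, 10 of 14 (11 adjusted over the list alone, adjusted p = 0.236 with an estimated correlation). Fasn went from 20.9 to 1020 CPM, and Pnpla3 and Elovl6 had log2 fold changes of 8.04 and 5.97. Of 8 PXR members 0 passed the gene test, and Cyp3a23/3a1 had a log2 fold change of −0.56 (adjusted p = 0.35). Of 14 CAR targets 3 rose and 1 fell (3 and 2 adjusted over the list alone), Gsta3 by 2.75 and Abcc3 by 2.67 up and Alas1 by −1.51, without a call for the list (adjusted p = 0.356), and Cyp2b1 had a log2 fold change of −0.62 (adjusted p = 0.611).

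Outside lipid synthesis, 5 of 14 p53 targets rose and 1 fell after atorvastatin (7 and 1 adjusted over the list alone, adjusted p = 0.325 with an estimated correlation), Cdkn1a from 4.91 to 29.7 CPM. Of 7 male-predominant genes 2 fell and 1 rose (4 and 1 adjusted over the list alone, adjusted p = 0.518 with an estimated correlation). Cyp2c11 fell from 1260 to 104 CPM. Erythroid markers fell, 3 of 4 (4 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation). The acetoacetyl-CoA synthetase gene Aacs rose from 1.37 to 194 CPM, and Lrtm2 (19.9 to 0.918 CPM) and the NADPH oxidase gene Nox4 (47.8 to 4.15 CPM) fell. In total 1040 genes rose and 588 fell. This count of 1628 rests on single animals: it was 3078 without atorvastatin replicate 4, 470, 719 and 635 without atorvastatin replicates 1, 2 and 3, and 581, 561 and 485 without vehicle replicates 1, 2 and 3.

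Phenobarbital, the prototype CAR activator, was given at 100 mg/kg per day for 7 days to 5 Han Wistar rats and compared with 5 vehicle rats. With all 10 animals, edgeR called 0 genes, DESeq2 called 648 and 2468 had an unadjusted p under 0.05. Cyp2b1, the classical CAR target, averaged 12200 ± 1120 CPM in treated rats and 2650 ± 5370 CPM in vehicle rats (SD, n = 5), a log2 fold change of 2.21 ± 1.3 (SE, adjusted p = 0.37). The CAR list was called higher with 0 of 14 members past the gene test (5 adjusted over the list alone, adjusted p = 0.269 with an estimated correlation), and the PXR list with 0 of 9 (4 up and 1 down adjusted over the list alone, adjusted p = 0.344 with an estimated correlation). Among vehicle rats, replicate 3 had 12300 CPM of Cyp2b1, within the range of treated rats (11500 to 14200), and the other 4 had 161 to 323. Without vehicle replicate 3, a choice made after this value was seen, 2092 genes were called, 1092 higher and 1000 lower. In that fit 13 of 14 CAR targets rose (13 adjusted over the list alone, adjusted p = 0.000514 with an estimated correlation). Cyp2b1 went from 247 ± 68 to 12200 ± 1120 CPM (log2 fold change 5.62 ± 0.216), Cyp2b2 from 234 to 6800 CPM, Abcc3 from 4.81 to 127 CPM, Cyp2c6v1 from 3050 to 16700 CPM, Gsta3 by 3.54, and Por, the P450 reductase, by 1.14. Of 27 NRF2 targets 17 rose and 1 fell (20 and 2 adjusted over the list alone, adjusted p = 0.00864 with an estimated correlation), with Akr7a3 at 2.65 and Ephx1 at 2.35. Of 9 PXR targets 4 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation), Cyp3a23/3a1 from 3350 to 15500 CPM and Cyp3a18 by −1.08. Cholesterol synthesis genes fell, 8 of 25 (13, with 1 higher, adjusted over the list alone, adjusted p = 0.248 with an estimated correlation), as did 7 of 17 hepatocyte genes (10 adjusted over the list alone, adjusted p = 0.181 with an estimated correlation), 6 of 12 macrophage markers (8 adjusted over the list alone, adjusted p = 0.248 with an estimated correlation) and 2 of 4 erythroid markers (3 adjusted over the list alone, adjusted p = 0.364 with an estimated correlation).

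Lapatinib, a kinase inhibitor of EGFR and ERBB2, was given at 500 mg/kg per day for 4 days, and the livers of the same 4 treated and 4 vehicle rats were measured in sequencing batches 1 and 10. In batch 1, edgeR called 0 genes, DESeq2 75, and 1117 had an unadjusted p under 0.05. Cyp1a1 averaged 8.58 CPM after lapatinib and 1.76 CPM in vehicle rats (log2 fold change 2.28, adjusted p = 0.41), and Cyp3a23/3a1 had a log2 fold change of 0.1. As lists, AhR targets (3 adjusted over the list alone, adjusted p = 0.113 with an estimated correlation), CAR targets (4 adjusted over the list alone, adjusted p = 0.637 with an estimated correlation) and cholesterol synthesis genes (1 adjusted over the list alone, adjusted p = 0.413 with an estimated correlation) were called higher, and macrophage markers (8 of 12 adjusted over the list alone, adjusted p = 0.276 with an estimated correlation) and proliferation genes (4 of 28 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation) lower, each with 0 members past the gene test. Without lapatinib replicate 1, 14 genes were called, and 1 without vehicle replicate 1 or 3 or lapatinib replicate 2 or 4. In batch 10, 40 genes were called, among them 2 of 12 macrophage markers lower (7 adjusted over the list alone, adjusted p = 0.481 with an estimated correlation) and 1 of 7 AhR targets higher (3 adjusted over the list alone, adjusted p = 0.195 with an estimated correlation).

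The difference of the lapatinib effect between the batches, tested with the replicate block, passed for 177 genes, 81 higher and 96 lower in batch 10. The share of calls that were higher was 45.8%, but 59.1% with RLE size factors and 61.3% with DESeq2. The nuclear receptor gene Rxra went from 160 to 136 CPM with lapatinib in batch 1 and from 28.6 to 48.1 CPM in batch 10, a difference of 0.98 ± 0.136 (SE, adjusted p = 0.00414, n = 4 per group), and the basement membrane collagen gene Col4a2 differed by 0.89. Lower in batch 10 were the histone methyltransferase gene Kmt2a (−1.86), the liver transcription factor gene Onecut1 (−1.64) and Lmbrd2 (−1.36). Of 29 PPARalpha targets 1 differed, Ehhadh (0.38), and 3 when adjusted over the list alone (adjusted p = 0.536 with an estimated correlation). Without the replicate block the count was 0 (1929 genes had an unadjusted p under 0.05 with it), and with RIN as a covariate it was 1. The mean RIN was 8.4 after lapatinib and 8.18 in vehicle rats in batch 1, and 7.55 and 6.55 in batch 10, so RNA integrity differed more between the arms in batch 10. The other gene table gave 52 and a fit across all animals 4. The count was 367, 54 and 56 without vehicle replicates 1, 2 and 4, and 95, 39, 29 and 40 without lapatinib replicates 1, 2, 3 and 4.

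**Figure D4:**
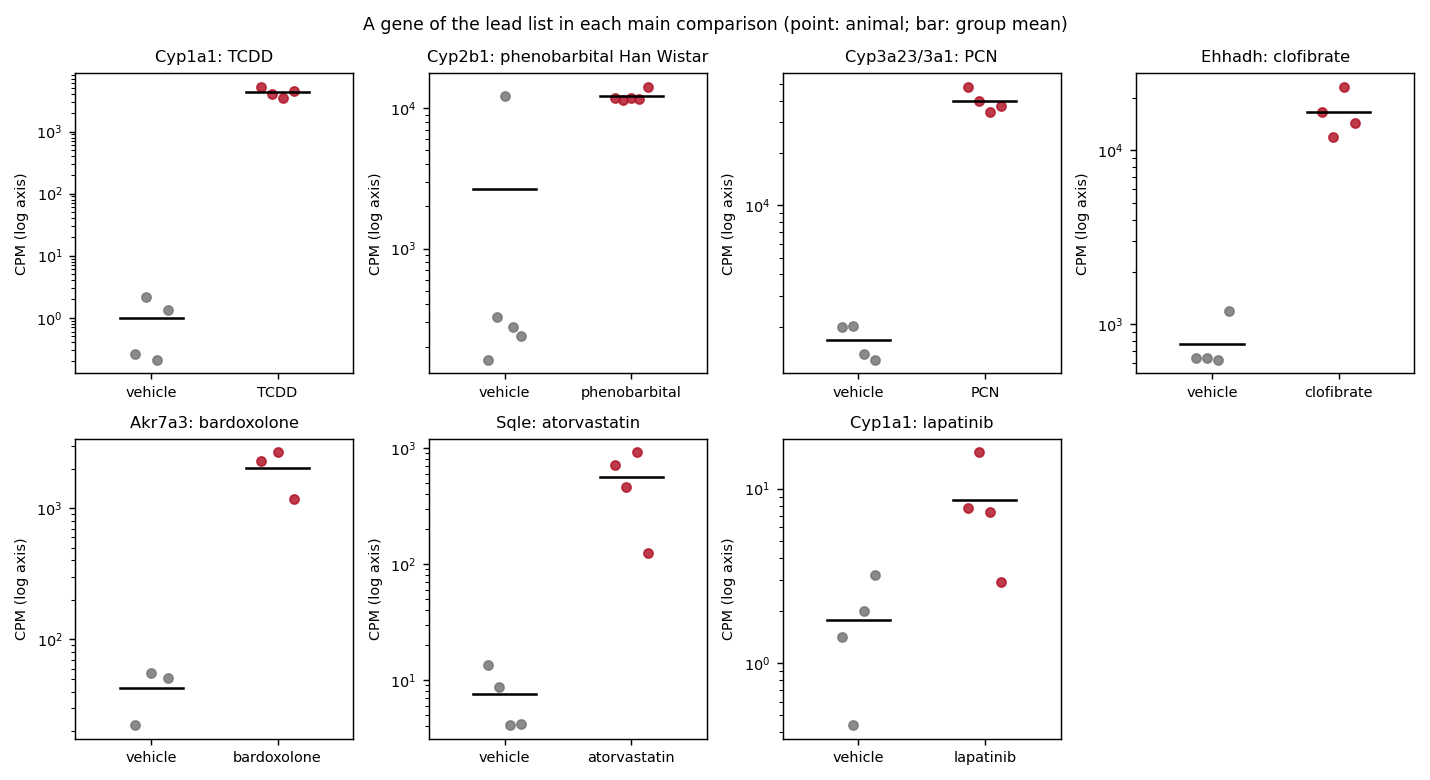
CPM (log axis) of a gene of the leading list in each of the 7 main comparisons, a point per animal and a bar at the group mean. Vehicle animals (grey) and treated animals (red) do not overlap except for Cyp2b1 in Han Wistar rats, where vehicle replicate 3 lies at 12300 CPM, and Cyp1a1 after lapatinib.

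Clarithromycin and erythromycin, macrolides that differ by a methyl group on a hydroxyl, were given at 600 mg/kg per day for 4 days in 1 study with a shared vehicle group. Cyp3a23/3a1 averaged 42200 ± 1380 CPM after clarithromycin, 5880 ± 1190 CPM after erythromycin and 3160 ± 384 CPM in vehicle rats (SD, n = 4 in each group), a difference of 2.84 ± 0.146 between the drugs (log2, SE, adjusted p = 6.73e-07). Ugt1a2 was at 277 against 6.4 CPM, Cyp2c24 at 118 against 9.01 CPM and Alas1, the rate-limiting enzyme of heme synthesis, at 1150 against 165 CPM. PXR targets were higher after clarithromycin, 6 of 9 (6 adjusted over the list alone, adjusted p = 0.000117 with an estimated correlation), as were 10 of 13 CAR targets (11 adjusted over the list alone, adjusted p = 0.0208 with an estimated correlation) and 17 of 27 NRF2 targets (19 adjusted over the list alone, adjusted p = 0.0243 with an estimated correlation). Hepatocyte genes were lower, 10 of 17 with 1 higher (13 and 1 adjusted over the list alone, adjusted p = 0.0208 with an estimated correlation), and so were Cyp4a1 (190 against 512 CPM, −1.43) and Cyp8b1, the sterol 12-hydroxylase of bile acid synthesis (−2.46). In all 1808 genes differed, 1012 higher and 796 lower after clarithromycin, and 1196 without clarithromycin replicate 2. A fit across all animals called 977.

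Telithromycin, a ketolide, and azithromycin, an azalide, were given at 600 mg/kg per day for 4 days to Sprague Dawley rats of different studies, and each effect was taken against its own vehicle group. Cyp3a23/3a1 went from 3500 ± 522 to 46900 ± 9960 CPM after telithromycin and from 4030 ± 721 to 484 ± 181 CPM after azithromycin (SD, n = 4 in each group), a difference of 6.8 ± 0.381 (log2, SE, adjusted p = 9.37e-08). Of 9 PXR targets 7 were higher after telithromycin (7 adjusted over the list alone, adjusted p = 0.000746 with an estimated correlation), among them Cyp3a18 (6.04) and Slco1a4 (4.21), and Cyp2b2 differed by 5.59. Interferon genes were all lower after telithromycin, 14 of 14 (14 adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation). The antiviral gene Rsad2 went from 3.84 to 445 CPM after azithromycin and from 4.4 to 2.19 CPM after telithromycin, and Isg15 from 5.69 to 423 CPM after azithromycin. Of 14 p53 targets 7 were lower after telithromycin (8 adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation), including Fas (−2.3). Of 7 male-predominant genes 6 were higher (6 adjusted over the list alone, adjusted p = 0.0417 with an estimated correlation), including Cyp2c11 (4.42). Macrophage markers were lower, 7 of 12 (9 adjusted over the list alone, adjusted p = 0.476 with an estimated correlation), and hepatocyte genes higher, 6 of 17 (10 adjusted over the list alone, adjusted p = 0.476 with an estimated correlation). In all 2970 genes differed, 1463 higher and 1507 lower after telithromycin.

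**Figure D5:**
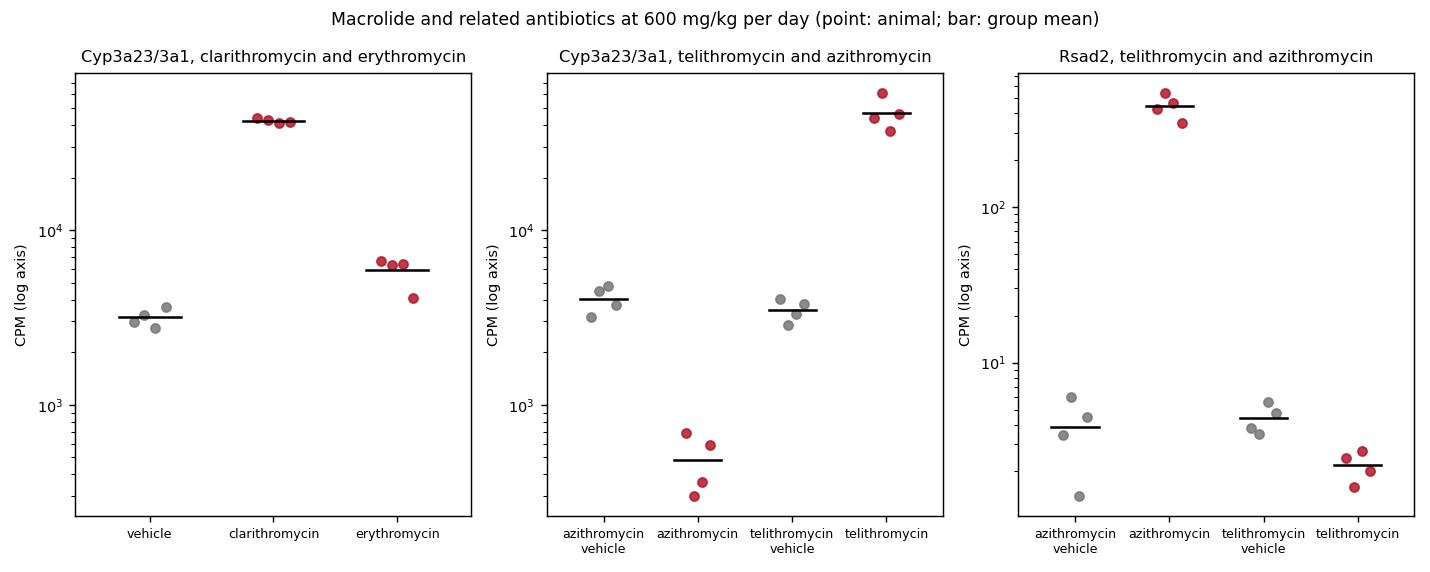
CPM (log axis) of Cyp3a23/3a1 in clarithromycin, erythromycin and vehicle rats, and of Cyp3a23/3a1 and Rsad2 in telithromycin and azithromycin rats with their vehicle groups; points are animals and bars group means. Cyp3a23/3a1 averages 42200 CPM after clarithromycin and 5880 CPM after erythromycin, and Rsad2 445 CPM after azithromycin against 2.19 CPM after telithromycin.

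LY2886721 and NB-360, known here by code names, were given at 750 mg/kg per day for 5 days in different studies with different vehicles. NRF2 targets were lower after LY2886721 than after NB-360, 21 of 27 (23 adjusted over the list alone, adjusted p = 0.00171 with an estimated correlation), each effect taken against its own vehicle group. Akr7a3 went from 44.6 to 160 ± 105 CPM after LY2886721 and from 37 to 2280 ± 927 CPM after NB-360 (SD, n = 4), a difference of −4.1 ± 0.634 (log2, SE, adjusted p = 0.00305). Cyp3a23/3a1 went from 3440 to 5330 CPM and from 3350 to 36100 CPM. In the PXR list 4 of 9 differed (5 adjusted over the list alone, adjusted p = 0.00171 with an estimated correlation), as did 6 of 14 CAR targets (8 adjusted over the list alone, adjusted p = 0.0332 with an estimated correlation) and 13 of 25 cholesterol synthesis genes (23 adjusted over the list alone, adjusted p = 0.0291 with an estimated correlation). PPARalpha targets were higher after LY2886721, 12 of 29 (20 adjusted over the list alone, adjusted p = 0.00171 with an estimated correlation), Cyp4a1 by 2.04, and so were 9 of 17 hepatocyte genes (13 adjusted over the list alone, adjusted p = 0.00586 with an estimated correlation). Proliferation genes were lower, 17 of 29 (26 adjusted over the list alone, adjusted p = 0.00964 with an estimated correlation), Top2a going from 5.96 to 0.781 CPM after LY2886721 and from 3.57 to 6.17 CPM after NB-360. Cyp17a1 (4.36) and Cyp2c12, a female-predominant P450 (−3.7), differed as well. In all 801 genes differed, 378 higher and 423 lower. The count was 496 without LY2886721 replicate 4 and 525 without NB-360 replicate 4. DESeq2 called 1241 and a fit with RIN as a covariate 296.

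Alpidem (600 mg/kg per day) and zolpidem (500 mg/kg per day), both imidazopyridines, were given for 4 days at different doses in different vehicles. The glucuronosyltransferase gene Ugt1a6 went from 11.7 to 229 ± 142 CPM after alpidem (n = 4) and from 23.9 to 42.9 ± 5.96 CPM after zolpidem (n = 3), a difference of 3.45 with a 95% interval from 2.11 to 4.79 (adjusted p = 0.0453). Slc16a6 was higher after alpidem (2.78), and the stress-induced cytokine gene Gdf15 (−2.89), the hepatokine gene Fgl1 (−2.13), the bile acid ligase Slc27a5 (−1.61) and the kininogen gene Kng1 (−1.48) were lower. Of 17 acute phase genes 3 were lower (3 adjusted over the list alone, adjusted p = 0.199 with an estimated correlation), and of 12 macrophage markers 1, Clec4f, at −1.16 (8 adjusted over the list alone, adjusted p = 0.277 with an estimated correlation). Cyp1a1 differed by 5.35 (95% interval from 2.55 to 8.15) with an adjusted p of 0.105. In all 40 genes differed, 25 higher and 15 lower after alpidem. DESeq2 called 345, the other gene table gave 85, a fit across all animals 65 and RIN as a covariate 9. Without alpidem vehicle replicates 1 and 3 the counts were 13 and 12, and without alpidem replicates 1, 3 and 4 they were 17, 15 and 10. They were 15, 8 and 99 without zolpidem vehicle replicates 1, 3 and 4, and without zolpidem replicates 1, 2 and 3 they were 105, 10 and 14.

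Omeprazole (750 mg/kg per day) and its S-enantiomer esomeprazole (600 mg/kg per day) were given for 4 days at different doses in different studies. No gene passed for the difference of their effects in edgeR, where 992 had an unadjusted p under 0.05, and DESeq2 called 51. The interval of the difference was wide for Cyp1a1 (1.48, 95% interval from −2.78 to 5.73) and narrower for Cyp3a23/3a1 (0.71, from 0.07 to 1.34), and its median half-width over all genes was 0.47. As lists, fatty acid synthesis genes (3 of 13 adjusted over the list alone, adjusted p = 0.00217 with an estimated correlation) and ATF4 stress response genes (10 of 20 adjusted over the list alone, adjusted p = 0.0475 with an estimated correlation) were higher after omeprazole, with 0 members past the gene test. A fit across all animals called 15 genes, and 17 were called without esomeprazole replicate 1 and 3 without omeprazole vehicle replicate 1.

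Cefprozil and cefuroxime, cephalosporins given at 600 mg/kg per day for 4 days in different studies, did not differ in any gene by edgeR, with 991 genes at an unadjusted p under 0.05 and 30 called by DESeq2. The difference was −0.42 for Cyp3a23/3a1 (95% interval from −0.93 to 0.09) and −0.21 for Cyp4a1 (from −1.32 to 0.9), and the median half-width over all genes was 0.53. Interferon genes were called higher after cefprozil (0 of 14 past the gene test, 0 adjusted over the list alone, adjusted p = 0.574 with an estimated correlation). The count was 1 without a count filter, 3 with the other gene table, and 44 in a fit across all animals. It was 1 without cefprozil replicate 1, cefprozil vehicle replicate 1 or cefuroxime vehicle replicate 1, and 2 without cefuroxime vehicle replicate 3 or cefuroxime replicate 2. The MK-3207 doses of 750 and 600 mg/kg per day, given in 1 study, also differed in 0 genes by edgeR, with 917 at an unadjusted p under 0.05, 16 by DESeq2, 21 in a fit across all animals and 1 without vehicle replicate 1. Between the doses Cyp3a23/3a1 differed by −0.11 (95% interval from −0.58 to 0.35) and Cyp4a1 by −0.13 (from −0.41 to 0.15), and the median half-width was 0.35. Cholesterol synthesis genes were called lower at the higher dose (0 of 25 past the gene test, 0 adjusted over the list alone, adjusted p = 0.721 with an estimated correlation).

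Phenobarbital at 100 mg/kg per day was also given to Sprague Dawley rats, for 17 days, with 2 treated and 3 vehicle animals. There Cyp2b1 went from 5.3 to 8230 CPM, a log2 fold change of 10.6 ± 0.582 (SE, adjusted p = 0.0048). The strains' effects, which also differ in duration, differed for 12 genes, 2 higher and 10 lower in Han Wistar rats. Here 1805 had an unadjusted p under 0.05 and DESeq2 called 208. Among the 12 were Sparc (−1.16), Serpinh1, a collagen chaperone (−1.57), and Tagln (−2.07), the 1 of 11 stellate and fibroblast markers that passed (7 adjusted over the list alone, adjusted p = 0.139 with an estimated correlation). The lipid desaturase gene Scd2 went from 11.6 to 129 CPM in Sprague Dawley rats and from 14 to 12.7 CPM in Han Wistar rats (−3.6 ± 0.383, adjusted p = 0.00182), and Evc differed by 3.01. Cyp2b1 differed by −8.37 (95% interval from −13.08 to −3.66) with an adjusted p of 0.145. This rests on Han Wistar vehicle replicate 3, whose Cyp2b1 value lay within the treated range, and without it the difference was −4.95 (adjusted p = 0.000118). The other gene table gave 54, a fit across all animals 202 and RIN as a covariate 3. The count was 36, 6, 70, 3 and 3 without Han Wistar vehicle replicates 1 to 5, and 2, 3, 3 and 3 without Han Wistar phenobarbital replicates 1, 2, 3 and 5. It was 7, 4 and 5 without Sprague Dawley vehicle replicates 1 to 3, and 278 without Sprague Dawley phenobarbital replicate 2, where the remaining treated animal is assumed to vary like the other groups.

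Repeat libraries of 1 animal show the size of technical differences. Within a batch number, the SD of log2 CPM differences over 8987 genes had a median of 0.247 in 48 pairs of libraries of 1 animal, and the rank correlation across genes a median of 0.993. Between batch numbers the median SD was 0.554 in 19 such pairs, above the 0.428 between different vehicle animals of 1 group (472 pairs) and the 0.435 between treated animals of 1 group (544 pairs).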

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

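Of the tests below, those of a treated animal under a vehicle label, of mixed RNA and of a swap were chosen only after the values of phenobarbital vehicle replicate 3 were seen, and the splits across treatments and of contrasts of 4 groups were extended after first runs with fewer, which across treatments were too few for a share under 0.05.

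In groups of 4 to 10 animals, a gap of the highest or lowest animal to the nearest other, divided by the range, was compared with Dixon's 95% critical value. Chance passes about 1 in 20 groups, and 22 of 286 combinations of a gene and a group passed (7.69%), with 3 of 26 group totals.

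In Han Wistar rats given phenobarbital, vehicle replicate 3 stood apart for Cyp2b1 (ratio 0.839; 12300 CPM against 161 to 323 in the other vehicle rats), Cyp2b2 (0.83; 7310 against 151 to 294) and Abcc3 (0.857; 124 against 3.64 to 6.08). Phenobarbital replicate 5 was the highest of its group for Cyp2b1 (0.832; 14200 CPM against 11500 to 11900). A swap between both groups would leave a treated library at the vehicle level, but the lowest treated Cyp2b1 value was 11500 CPM. Vehicle RNA mixed with RNA of a treated animal would lie below the treated libraries. Over 210 genes that rose, replicate 3 lay at a median of 1.06 on a scale from the vehicle mean (0) to the treated mean (1), where treated libraries spanned 0.723 to 1.39. Over 168 genes that fell it lay at 0.992, so a treated animal or its RNA may carry the vehicle label. Its library had a noise index of 6.12 to phenobarbital replicate 1, with other treated libraries up to 31.3. Treated libraries gave 18.2 to 35 among themselves, and libraries of 1 animal in 1 batch number a median of 3.45 and at most 13.8. Different treated animals of 1 group gave at least 14.3 outside the PCN study, whose shallow libraries reached 4.91. A candidate explanation is therefore that RNA of phenobarbital replicate 1 was sequenced a second time under the vehicle label; these libraries are not identical columns. No biological explanation was tested. Among 100 splits of these 10 animals all 100 gave at least the real count of 0 genes, and the highest other gave 2036, which points to a structure of the samples.

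After atorvastatin, replicate 4 was the lowest treated animal for 4 lipid genes: Acat2 (0.901; 37.8 CPM against 291 to 364), Pnpla3 (0.887; 4.15 against 71.1 to 102), Fasn (0.85; 170 against 1110 to 1550) and Elovl6 (0.877; 7.24 against 73.4 to 101). Vehicle replicate 4 of that study was low for Nox4 (0.925). In the PCN study a single animal stood apart for Gsta3 (vehicle replicate 2, 0.903), Msmo1 (PCN replicate 1, 0.883), Cyp17a1 (vehicle replicate 3, 0.867) and Abcg8 (vehicle replicate 4, 0.923), and in the clofibrate study for Ehhadh and Cyp4a1 (vehicle replicate 4, 0.968 and 0.852) and Cyp1a2 (vehicle replicate 1, 0.865). The others were Tiparp in TCDD vehicle replicate 1 (0.848), Cyp3a23/3a1 in erythromycin replicate 4 (0.903; 4100 CPM against 6340 to 6650), Cyp4a1 in vehicle replicate 4 of the clarithromycin study (0.93), Ccng1 in azithromycin vehicle replicate 4 (0.897), Cyp17a1 in LY2886721 vehicle replicate 2 (0.848) and Slc16a6 in alpidem vehicle replicate 2 (0.944). Library totals stood apart in PCN vehicle replicate 2 (0.934; 10 M counts against 1.33 to 1.52), clarithromycin replicate 3 (0.995; 20.6 against 17.9 to 18) and zolpidem vehicle replicate 3 (0.88; 22.8 against 26.3 to 26.8).

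The phenobarbital effect differed between strains (Han Wistar minus Sprague Dawley, log2, tested as a difference of effects) for Evc (3.01), Agxt (1.28), Plxnd1 (−1.06), Sparc (−1.16), Fstl1 (−1.3), Dchs1 (−1.48), Serpinh1 (−1.57), Vnn1 (−1.92), Tagln (−2.07) and Scd2 (−3.6). Days of dosing also differ between these studies, and the Sprague Dawley arm has 2 treated animals. The lapatinib effect differed between batches 10 and 1 for 177 genes. Almorexant was also sequenced in batch 2, with 3 treated libraries and 1 vehicle library, too few for the comparisons. These come from animals also sequenced in batch 10, so agreement is no independent test: of the 4481 genes called in batch 10, 4442 (99.1%) had the same direction there, with Cyp1a1 at 575 to 2570 against 1.13 CPM.

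Other splits of the same animals were counted for each number of genes called, the real split included. Chance was excluded where only 1 of 35 splits, the real one, gave as many. These were TCDD (2673, highest other 1), PCN (451, 1), clofibrate (1861, 3) and atorvastatin (1628, 14). Others were clarithromycin minus erythromycin (1808, 2) and the lapatinib repeat (177, 11). Chance was also excluded for the 59 comparisons that reached 100 genes across treatments (1 of 21, highest other 1). Splits within studies test for any treatment effect, not for a difference. Of 100, 1 gave as many for telithromycin minus azithromycin (2970, highest other 2059, which can hold a treatment effect). The same held for LY2886721 minus NB-360 (801, 13) and alpidem minus zolpidem (40, 30). For bardoxolone 10 splits are too few for a share under 0.05 (1 of 10, real 3635, highest other 0). Real counts of 0 in edgeR were matched by every split: 35 of 35 for lapatinib (1117 genes at an unadjusted p under 0.05, 75 by DESeq2; highest other 3) and for MK-3207 (917 and 16; highest other 2), and 100 of 100 for the cephalosporins (991 and 30; highest other 3) and omeprazole minus esomeprazole (992 and 51; highest other 427, which can hold a treatment effect in the same way).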

How the results depend on the processing

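Chosen only after the data were seen were the leave-out runs of every comparison across treatments, the troglitazone run and the alternatives for the strain comparison.

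RLE size factors left all 24 counts within 1.5 times the value reported, kept all 156 list calls and changed 5 of 546 gene calls. Removing libraries of RIN under 7 (7 counts) and pairing with the nearest control library (1 count) also left counts within 1.5 times. Of 156 list calls, 152 held without a count filter, 147 with the other gene table, 131 with RIN as a covariate, 71 by fry and 21 with an estimated correlation, and in runs without 1 animal 1649 of 1817 held. Over all alternatives 7594 of 8901 gene values kept direction and side of the threshold, 1208 fell short of it, 71 passed it, 28 moved without a test and 0 reversed.

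Requiring an absolute log2 fold change of at least 1, which can only lower a count, gave 446 genes for TCDD, 211 for PCN, 396 for clofibrate, 821 for bardoxolone, 575 for atorvastatin, 29 for the lapatinib repeat, 284 for clarithromycin minus erythromycin, 1451 for telithromycin minus azithromycin, 358 for LY2886721 minus NB-360 and 425 for the strains' vehicle rats. RIN as a covariate, which takes a degree of freedom and follows the arms where RIN differs, gave 49 for TCDD, 16 for bardoxolone, 1 for the lapatinib repeat, 296 for LY2886721 minus NB-360, 9 for alpidem minus zolpidem and 3 for phenobarbital between strains. DESeq2 gave 648 for phenobarbital in Han Wistar rats, 75 for lapatinib, 16 for MK-3207, 30 for the cephalosporins, 1241 for LY2886721 minus NB-360, 51 for omeprazole minus esomeprazole, 345 for alpidem minus zolpidem and 208 for phenobarbital between strains. 1 fit across all animals gave 532 for phenobarbital in Han Wistar rats, 775 for PCN, 2232 for bardoxolone, 2664 for atorvastatin, 6 for lapatinib, 4 for the lapatinib repeat, 21 for MK-3207, 977 for clarithromycin minus erythromycin, 44 for the cephalosporins, 15 for omeprazole minus esomeprazole, 65 for alpidem minus zolpidem and 202 for phenobarbital between strains. The other gene table gave 52 for the lapatinib repeat, 3 for the cephalosporins, 85 for alpidem minus zolpidem and 54 for phenobarbital between strains. No count filter gave 6 for lapatinib and 1 for the cephalosporins. Bardoxolone had 1825 without the sex covariate, and the lapatinib repeat 0 without the replicate block. Where no reason is given, the cause was not tested.

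With RIN as a covariate the direction of 7 lists reversed, given with adjusted p: cholesterol synthesis after TCDD (0.178), PPARalpha (0.166), ATF4 (0.857) and ER chaperones (0.035) after bardoxolone, ER chaperones (0.57) and interferon (0.0677) after lapatinib, and NRF2 for alpidem minus zolpidem (0.295); the cause was not tested. Comparisons with a list called higher fell with an estimated correlation from 55 to 6 for AhR, 67 to 17 for CAR, 45 to 6 for PXR, 16 to 1 for PPARalpha, 68 to 6 for NRF2 and 45 to 0 for cholesterol synthesis, and by fry to 5 for PPARalpha and 15 for cholesterol synthesis.

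Leaving out 1 animal at a time, counts ran from 1684 to 2565 for TCDD, 0 to 2092 for phenobarbital in Han Wistar rats, 346 to 460 for PCN, 812 to 2223 for clofibrate, 2097 to 3006 for bardoxolone, 470 to 3078 for atorvastatin, 0 to 14 for lapatinib, 29 to 367 for the lapatinib repeat, 0 to 1 for MK-3207, 1196 to 1817 for clarithromycin minus erythromycin, 2305 to 3661 for telithromycin minus azithromycin, 0 to 2 for the cephalosporins, 496 to 919 for LY2886721 minus NB-360, 0 to 17 for omeprazole minus esomeprazole, 8 to 105 for alpidem minus zolpidem and 2 to 278 for phenobarbital between strains, the 278 with 1 treated Sprague Dawley animal left. Troglitazone went from 0 to 84 without its replicate 1.

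Depth limited the PCN study most: its fit tested 7361 genes, where the comparisons across treatments tested up to 13442.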

Other observations

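The strain comparison, the tests on the TCDD clock genes, the 50% bound on immune cell markers as an exclusion, the search for matched animals and the troglitazone fit without replicate 1 were chosen only after the data were seen.

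Vehicle rats of both strains differed in many genes. With studies as replicates (13 Han Wistar studies of 52 animals, 22 Sprague Dawley studies of 85; males, batch 3, day 4 and 1 vehicle), edgeR called 5526 of 14470 genes, 2520 higher and 3006 lower in Han Wistar rats, and 206 of them did not overlap between the strains' studies. With an absolute log2 fold change of at least 1 the count was 425. Of 100 splits of the studies 1, the real one, gave as many (highest other 311), which excludes chance. Aldh1a7 was at 0.121 CPM in Han Wistar and 16.4 CPM in Sprague Dawley rats (SD 0.0299 and 7.54; log2 difference −7.1 ± 0.272, adjusted p = 4.58e-21), Cyp2c12 at 38.1 and 255 CPM and Aox2 at 10.5 and 1.01 CPM. Of 12 clock genes 4 were higher and 6 lower in Han Wistar rats (the same adjusted over the list alone), Nr1d1 by −4.51, Dbp by −3.5, Per3 by −3.18 and Cry1 by 2.52, without a call for the list (adjusted p = 0.0528, and 0.416 with an estimated correlation). Of 14 interferon genes 11 were lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation), 8 of 11 lymphocyte markers were lower (10 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), and 10 of 17 hepatocyte genes were higher (11 adjusted over the list alone; adjusted p = 0.0731 with an estimated correlation). No study holds both strains, so strain and study conditions such as the hour of collection were not separated.

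TCDD rats had a clock score of 2.45 ± 0.63 and their vehicle rats −2.98 ± 0.619 (SD, n = 4 each). The difference was 5.43. The score holds only clock genes called after TCDD. The 82 vehicle groups of other studies ran from −3.58 to 3.73. RNA quality differed (RIN 1.32 higher after TCDD), but within other vehicle groups the score fell with RIN (slope −0.377 ± 0.203 SE). The predicted difference was at most 0.0389. Livers taken at another hour or feeding state may differ in these genes. On the line along which vehicle groups of both strains differ, changes of the 12 clock genes were predicted at the TCDD score difference. They correlated at 0.834 with the observed ones. This value is partly fixed in advance, since all but Per1, Cry1 and Nr1d1 are in the score. Of those, Per1 changed by 0.22 against a predicted 0.11, Nr1d1 by 0.96 against 5.11 and Cry1 by −0.43 against −2.86. The line also carries the strain difference above. On a line over the 41 Han Wistar vehicle groups of other studies the correlation, with the same limit, was 0.724. These groups spanned only −3.58 to −1.32, so the TCDD score lies outside them. TCDD and the hour of collection cannot be told apart, since the labels give no hour. Of the 2673 genes called after TCDD, the first line predicted at least 50% of the change for 827 (30.9%) and the second for 1004 (37.6%), and neither did for any of the 6 AhR targets called. Both predictions take the whole TCDD score difference as lying on the line.

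After azithromycin the interferon score was 7.75 ± 0.277 against 3.49 ± 0.967 in vehicle rats (SD, n = 4 in each group), a difference of 4.26, and 0 of the 739 other libraries reached the lowest azithromycin value of 7.44 (highest 6.31). RNA quality predicted at most 0.0288. More immune cells may bring interferon genes. As the whole cause they would need marker medians of at least 1.5, 50% of the interferon median of 3. Macrophage markers had a median log2 fold change of 0.31 (SD of members 0.589, from −0.85 to 1.15; 4 up and 2 down of 12, and 5 and 2 adjusted over the list alone) and lymphocyte markers of 0.25 (SD 0.217, from 0.01 to 0.44; 0 of 4 past the gene test), and neither list was called (adjusted p = 0.557 and 0.816). All 16 lie below 1.5, a bound set after seeing the data, which argues against more of these cells as the whole cause. Both medians lay above 0, so a smaller contribution stays open. Endothelial markers fell in the same livers, 8 of 9 (8 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation), as did 15 of 17 hepatocyte genes (15, with 1 higher, adjusted over the list alone, adjusted p = 0.0661 with an estimated correlation), and which cells carry the interferon genes was not separated.

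Among libraries within a root-mean-square log2 CPM difference of 0.36, those of different animals matched as closely as repeats of 1 animal in 24 pairs of animals (noise index 1.74 to 6.12, the next pair within this limit at 12.8). Different animals of 1 group had indices from 3.12 in the shallow PCN study and from 13.5 in all other studies. Of these, 22 pairs were vehicle animals of 6 pairs of studies with the same replicate and animal numbers, and 1 study pair carried 2 vehicle names, so some vehicle groups of different studies are not independent. The others were phenobarbital replicate 1 with vehicle replicate 3, and troglitazone replicate 1 with vehicle replicate 4 (3.71). With every animal, troglitazone changed 0 genes in edgeR (1333 at an unadjusted p under 0.05, 65 by DESeq2). Without its replicate 1 it changed 84, 63 higher and 21 lower. Of 25 cholesterol synthesis genes 18 rose (25 adjusted over the list alone). With an estimated correlation p was 0.00979, adjusted over this fit's lists only.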
